A study of Homo sapiens with 36 samples.

How the data were processed

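RNA-seq was measured in 36 libraries of THP-1 cells, wild type or IRG1 (ACOD1) knockout, differentiated with PMA and given vehicle or LPS with interferon-gamma for 6, 12 or 24 h, with 3 libraries per group. Values are log2 expression values deposited by the authors in 1 table, used without further transformation. Per the submitters' processing notes, GSNAP, cutadapt 1.9.1 and the genome build GRCh37.p5 were used. Their order, the counting tool, the gene annotation, the offset added before the logarithm and the normalization are not given. The table held 21599 Entrez Gene rows with no missing value, of which 20609 matched a gene symbol and 990 did not. Library medians ran from 5.4691 to 5.4753 and 88.0% of ranks differed by less than 0.1 between libraries, so the libraries share nearly 1 distribution of values. Values ran from -0.34 to 16.75, 7744 were exactly 0 and 274 were below 0. Read counts are not part of the table, so sequencing depth and the precision it gives are unknown. No interval or floor from depth is given. Genes at or above log2(10), which is 3.32, in at least 3 libraries were kept, 21232 in all, with 15289 protein-coding genes, 2428 pseudogenes and 1870 long noncoding RNAs, and 367 were removed.

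A linear model with 12 group means was fitted to all 36 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with a mean-variance trend), with 24 residual degrees of freedom and a median prior of 4.45. The 20 comparisons were stimulated against vehicle in each genotype and time, KO against WT in each treatment and time and on the mean of 3 times, the interaction of genotype and treatment at each time and on the mean, and the response at 24 h against 6 h in each genotype. Within each comparison p-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p below 0.05 with no minimum fold. Of 29 gene lists fixed in advance, 28 were tested, since none of the 13 members of the mitochondrially encoded list matched. List tests used camera with a preset correlation of 0.01, again with the correlation estimated from the data, and fry, adjusted over 560 tests. Of these list tests (list by comparison) 249 were called with the preset correlation, of which 41 held and 208 were lost with the estimated one, and 187 were called by fry in the same direction. Counts adjusted over the list alone use Benjamini-Hochberg over the members only. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for tables and figures, and GENCODE 29 for gene types, length and GC content. Linear folds are given only where both group means reach log2(10).

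Comparisons, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names ACOD1 in every library, then TNF, IL6, IL1B, IL10, IL12B, CXCL10, IFNB1 and HMOX1 in every comparison, then the 6 largest rises and 6 largest falls per comparison among called genes whose group values do not overlap, leaving out uncharacterized loci, antisense genes, pseudogenes and small RNAs, and then for each list described up to 4 members with the largest absolute change. Rises and falls were ranked on the mean change over the 3 times among genes called at all 3, and for the interaction and the 24 h against 6 h response on the single tested change. The analysis was tested on simulated data: of 100 genes shifted by log2 1, 23 were recovered, of 100 shifted by log2 2, 70 were recovered, 0 had the wrong direction, and 7 false calls were made, with 0 in an unchanged comparison. In the same data the shifted list was called and 0 of the other lists. Replicate numbers were checked as pairs: in 9 of 12 comparisons every pair of like-numbered libraries correlated over 0.1 after removal of group means, and over all comparisons the pairs ran from -0.150 to 0.589. Alternatives were no filter, a stricter filter (mean at or above the median of kept genes), a pseudocount of 5, quantile normalization, median centring, no mean-variance trend, library weights, a fit of only the libraries compared, a replicate block, a minimum log2 change of 1 and each library left out in turn, the last also for lists in the genotype comparisons. Leaving out 2 or 4 doubted libraries was added after seeing the data. List members without a matched row, among them AKR1B10 and CRYAB, are not used here. Some genes that the rule would name are not reported here.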

Results

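The 36 RNA-seq libraries came from PMA-treated THP-1 macrophages, wild type (WT) or IRG1 knockout (KO). They were given vehicle or LPS with interferon-gamma for 6, 12 or 24 h (n = 3 in each of 12 groups). IRG1 is the older name of ACOD1, the enzyme that makes itaconate from cis-aconitate. Values are deposited log2 values, a standard error follows ± after a log2 change, an SD follows ± after a level, and sets of 3 values run in the order 6, 12 and 24 h. Brackets after a left-out library hold the log2 change, list median or gene count without it. A gene is called at a limma adjusted p below 0.05. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples. Sequencing depth is unknown.

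ACOD1 was close to 0 in vehicle-treated cells and reached high values with stimulation in both genotypes. In the WT vehicle libraries ACOD1 read 0.41, 0.19 and 0.19 at 6 h, 0.43, 0.26 and 0.12 at 12 h and 0.59, 0.86 and 0.32 at 24 h. The KO vehicle libraries read 0.04, 0.12 and 0.00, then 0.03, 0.33 and 0.01, then 0.03, 0.32 and 0.03. With stimulation the WT libraries read 12.76, 11.49 and 11.11 at 6 h, 11.97, 11.80 and 11.00 at 12 h and 10.95, 10.96 and 9.20 at 24 h. The stimulated KO libraries read 8.35, 8.31 and 8.80 at 6 h, 7.98, 10.22 and 8.49 at 12 h and 8.31, 9.78 and 8.60 at 24 h. The ACOD1 transcript was thus lowered and not absent in stimulated KO cells. It was 9.89-fold lower than in WT at 6 h (-3.31 ± 0.47, adjusted p = 3.74e-05) and 6.47-fold lower at 12 h (-2.69 ± 0.47, adjusted p = 8.70e-04), and not called at 24 h (-1.48 ± 0.47, adjusted p = 0.0597). At 24 h ACOD1 passed the test without KO replicate 2 (-1.92) or WT replicate 3 (-2.06) or with a replicate block (adjusted p = 0.0264). With only the libraries compared the 12 h call was lost.

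**Figure D1:**
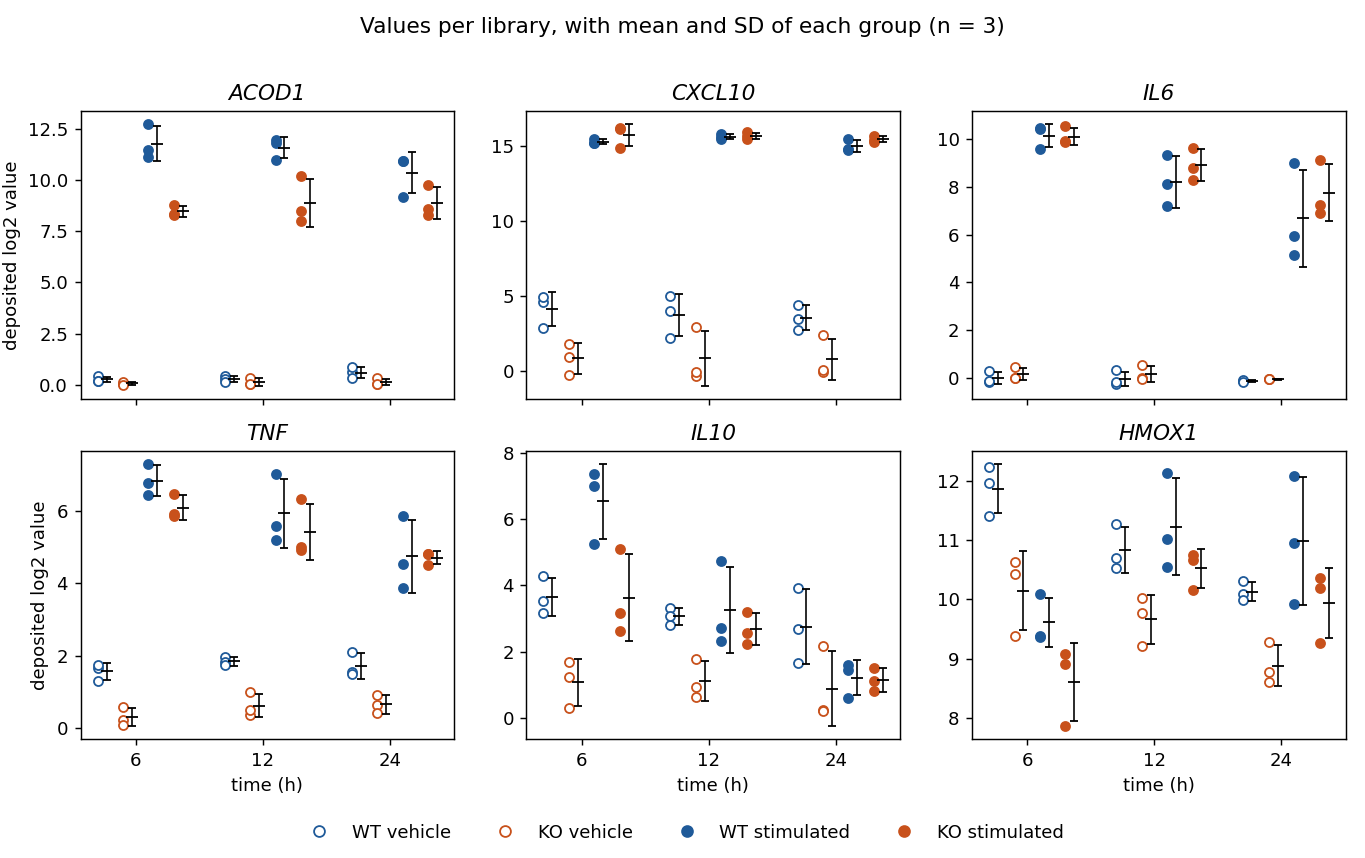
Deposited log2 values (vertical axis) of ACOD1, CXCL10, IL6, TNF, IL10 and HMOX1 against time in h for each library (points, open for vehicle and filled for stimulated, blue WT and orange KO), with mean and SD of each group (bars, n = 3). ACOD1 with stimulation was 11.79 ± 0.86 in WT and 8.48 ± 0.27 in KO cells at 6 h.

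The first question was how each genotype answered LPS with interferon-gamma at each time. Chemokines had the largest rises. CXCL9, which draws activated T cells, rose by 14.26, 14.37 and 14.82 in WT cells and by 16.24, 16.88 and 15.53 in KO cells. In WT cells at 6 h it went from 0.48 ± 0.72 to 14.74 ± 0.19 (n = 3). CXCL10 rose by 11.16, 11.86 and 11.42 in WT and by 14.90, 14.83 and 14.67 in KO cells. CXCL11 rose by 11.31, 11.18 and 10.36 and by 13.69, 13.55 and 13.14. The monocyte attractant CCL8 (11.75, 12.39 and 11.70 in WT, 13.48, 12.84 and 11.79 in KO cells) and the lymph node homing receptor CCR7 (10.91, 11.07 and 10.61, and 10.61, 11.29 and 12.06) rose in both genotypes. ACOD1 completed the 6 largest rises in WT cells (11.52, 11.32 and 9.78, against 8.43, 8.77 and 8.76 in KO cells). The adhesion molecule VCAM1 completed those in KO cells (11.23, 11.37 and 11.45). The 6 largest falls in WT cells included the receptors GPR82 (-5.94, -6.89 and -6.79), GPR34 (-5.10, -5.57 and -5.88) and FFAR4 (-5.19, -5.16 and -4.98). The other 3 were TMEM37 (-5.59, -5.47 and -6.30), LINC01736 (-5.35, -4.51 and -6.51) and KLRC4 (-3.0, -5.31 and -6.73). In KO cells they were in DLX3 (-7.55, -7.19 and -7.41), RGS4 (-5.21, -6.35 and -7.08) and PCARE (-5.88, -5.83 and -6.37), followed by FOXO6 (-5.10, -5.89 and -5.37), ELFN2 (-4.90, -5.67 and -5.65) and PRAM1 (-6.13, -5.14 and -4.45).

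Among the cytokines fixed beforehand, IL6, which drives the acute phase response, rose from -0.01 ± 0.24 to 10.16 ± 0.49 in WT cells at 6 h. Changes in WT cells were IL6 (10.17, 8.25 and 6.83), TNF (5.26, 4.08 and 3.03), IL1B (6.67, 5.28 and 6.19), IL12B (7.20, 5.98 and 2.46, called at 6 h and 12 h) and IFNB1 (5.44, 4.91 and 3.64). Those in KO cells were IL6 (9.97, 8.74 and 7.83), TNF (5.77, 4.79 and 4.04), IL1B (5.94, 4.41 and 5.48), IL12B (5.60, 4.44 and 2.96) and IFNB1 (5.48, 2.92 and 2.43, called at 6 h and 12 h). The anti-inflammatory cytokine IL10 rose at 6 h alone, by 2.87 in WT and 2.55 in KO cells. HMOX1, which degrades heme, fell at 6 h alone, with -2.25 and -1.54. Later values were not called for IL10 (0.20 and -1.54 in WT, 1.56 and 0.27 in KO cells) or HMOX1 (0.39 and 0.86, and 0.86 and 1.06). IL10 in WT cells at 24 h gained a call without vehicle replicate 2 (-2.09). In WT cells at 24 h IL12B gained a call without stimulated replicate 3 (3.58) and HMOX1 without stimulated replicate 2 (1.38). HMOX1 in KO cells at 6 h lost its call without stimulated replicate 1 (-1.16). IL1B and IL12B in KO cells at 12 h lost their calls without stimulated replicate 2 (3.0 and 2.69). IFNB1 in KO cells at 12 h lost its call without vehicle replicates 1 (3.01) and 3 (2.46) or stimulated replicates 2 (1.77) and 3 (2.94). IL12B in KO cells at 24 h lost its call without vehicle replicates 1 (2.88), 2 (3.12) and 3 (2.88) or stimulated replicate 2 (1.56). At 24 h in KO cells IFNB1 gained a call without stimulated replicate 3 (3.64) and HMOX1 without stimulated replicate 2 (1.40). Under other settings calls were lost, with only the libraries compared IL10 (KO 6 h), IFNB1 (KO 12 h) and IL12B (KO 24 h), and with a pseudocount of 5 IL12B (KO 24 h), and with 4 doubted libraries left out IL10 (KO 6 h). A replicate block gained calls (adjusted p in brackets) for IL12B (WT 24 h 0.02503), IFNB1 (KO 24 h 0.0306) and HMOX1 (KO 24 h 0.0264). Also gained: IL10 (KO 12 h) and HMOX1 (KO 12 h and KO 24 h) with only the libraries compared; IL12B (WT 24 h) with 2 or 4 doubted libraries left out.

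Inflammatory gene groups were called up in both genotypes at all 3 times. Proinflammatory cytokines rose in 14 to 19 of 23 in WT and 13 to 21 in KO cells (15 to 19 and 14 to 21 adjusted over the list alone). IL32 (5.71, 7.13 and 6.96) and TNFSF10 (6.53, 6.47 and 5.84) stood beside IL6 in WT cells, and this list call held at 6 h and 12 h (adjusted p = 0.00509 to 0.0778 with an estimated correlation). Chemokines rose in 20 to 21 of 24 in WT and 21 to 22 in KO cells (21 to 22 and 22 to 23 adjusted over the list alone). Their medians were 6.31 and 7.62 at 6 h (adjusted p = 1.95e-05 to 4.17e-04 with an estimated correlation). NF-kB feedback and target genes rose in 29 to 30 of 30 in WT and 29 to 30 in KO cells (29 to 30 and 29 to 30 adjusted over the list alone). The hyaluronan binder TNFAIP6 (8.69, 9.47 and 10.49) and the costimulator CD80 (9.42, 9.71 and 9.29) led in WT cells (adjusted p = 1.03e-05 to 3.89e-05 with an estimated correlation). Anti-inflammatory mediators rose in 12 to 14 of 16 in WT and 12 to 14 in KO cells (12 to 14 and 14 to 15 adjusted over the list alone). The tryptophan-degrading enzyme IDO1 (9.54, 9.89 and 9.89) and the checkpoint ligand CD274 (7.58, 7.90 and 7.65) led there (adjusted p = 0.00134 to 0.00974 with an estimated correlation). Interferon-gamma-induced GTPases and regulators rose in 23 to 27 of 28 in WT and 26 to 28 in KO cells (23 to 27 and 26 to 28 adjusted over the list alone). In front were GBP5 (8.17, 8.21 and 9.47) and GBP4 (7.14, 7.12 and 7.25) in WT cells (adjusted p = 5.76e-04 to 0.00477 with an estimated correlation). Antigen presentation genes rose in 22 to 24 of 27 in WT and 25 to 26 in KO cells (23 to 24 and 25 to 26 adjusted over the list alone). They included HLA-DQA1 (6.65, 8.33 and 8.00) and HLA-DRA (7.11, 7.82 and 7.12) in KO cells, and the WT call held at 12 h only (adjusted p = 0.00666 to 0.0699 with an estimated correlation). Interferon-stimulated genes, the antiviral effectors, rose in 37 to 40 of 40 in WT and 40 in KO cells (37 to 40 and 40 adjusted over the list alone). They included RSAD2 (6.09, 6.32 and 7.05) and ISG20 (6.58, 6.43 and 6.43) in WT and IFI44L (6.97, 7.57 and 8.17) and OASL (7.99, 7.25 and 7.23) in KO cells. This list call was lost (adjusted p = 0.0681 to 0.169 with an estimated correlation). Immediate early genes rose in 10 to 14 of 20 in WT and 12 to 15 in KO cells (11 to 15 and 12 to 15 adjusted over the list alone), with NR4A3 (5.65, 5.51 and 5.56) and MAFF (4.00, 4.88 and 5.21) in WT cells. This call was lost too (adjusted p = 0.0573 to 0.132 with an estimated correlation). Inflammasome and pyroptosis genes rose in 12 to 13 of 22 in WT and 11 to 13 in KO cells (12 to 14 and 12 to 13 adjusted over the list alone), with AIM2 (5.07, 5.29 and 5.80) in WT cells, and this call was lost (adjusted p = 0.0704 to 0.125 with an estimated correlation). Genes of TLR and interferon receptor signalling rose in 12 to 18 of 35 in WT and 13 to 15 in KO cells (12 to 18 and 13 to 15 adjusted over the list alone). The receptor adaptor IRAK2 (5.03, 4.74 and 5.35) and the coreceptor CD14 (-2.61, -2.51 and -2.39) changed most in WT cells, and the call was lost (adjusted p = 0.367 to 0.604 with an estimated correlation).

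The ubiquitin system changed in parts. Ubiquitin ligases, which choose the proteins to be tagged, were called up as a list and rose in 20 to 22 of 50 in WT and 19 to 20 in KO cells (20 to 23 and 19 to 21 adjusted over the list alone). Members that fell numbered 4 to 5 and 6 to 7, and the call was lost at each time (adjusted p = 0.367 to 0.446 with an estimated correlation). The largest ligase changes in WT cells were NEURL3 (7.88, 7.84 and 7.96), RNF19B (4.59, 5.15 and 5.02), RNF125 (-4.26, -4.49 and -4.06) and RNF213 (2.96, 3.30 and 3.36). The ubiquitin, E1 and E2 list was not called and rose in 11 to 14 of 37 in WT and 9 to 12 in KO cells (12 to 15 and 9 to 12 adjusted over the list alone). The largest changes in WT cells were UBE2L6 (2.56, 2.47 and 2.48) and UBE2E2 (1.5, 1.52 and 1.64). Deubiquitinases, which remove the tag, were not called either and rose in 10 to 11 of 42 in WT and 11 to 12 in KO cells (10 to 11 and 10 to 13 adjusted over the list alone). They fell in 9 to 11 and 4 to 10, and STAMBPL1 (3.45, 3.90 and 3.36) and CYLD (2.96, 2.51 and 2.38) changed most in WT cells. The proteasome list was called up in KO cells at 6 h only, where 6 of 31 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.15, adjusted p = 0.751 with an estimated correlation). In WT cells PSMA2 (2.29, 2.29 and 1.34) and PSMA4 (1.81, 1.79 and 1.54) changed most.

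Lists of mitochondrial and cell cycle genes were called down, and none of these calls held with an estimated correlation. TCA cycle genes fell in 16 to 22 of 28 in WT and 12 to 15 in KO cells (16 to 23 and 13 to 15 adjusted over the list alone) and rose in none. The carrier SLC25A10 (-2.35, -2.72 and -3.44) and the carboxylase PC (-2.56, -3.37 and -2.40) fell most in WT cells (adjusted p = 0.0771 to 0.391 with an estimated correlation). Oxidative phosphorylation genes fell in 7 to 26 of 30 in WT and 8 to 21 in KO cells (7 to 26 and 8 to 23 adjusted over the list alone). This list was called at 12 h and 24 h only (adjusted p = 0.306 to 0.630 with an estimated correlation). Cell cycle genes fell in 21 to 32 of 32 in WT and 26 to 31 in KO cells (28 to 32 and 28 to 32 adjusted over the list alone). In WT cells MCM6 (-3.0, -3.17 and -3.34) and E2F1 (-2.38, -3.21 and -3.93) fell most (adjusted p = 0.266 to 0.458 with an estimated correlation). Integrated stress response genes, which follow amino acid shortage and misfolded protein, were called up at 24 h only. In WT cells 18 of 27 rose and 1 fell (19 and 1 adjusted over the list alone, median 1.70, adjusted p = 0.293 with an estimated correlation). In KO cells 21 of 27 rose and 0 fell (21 and 0 adjusted over the list alone, median 2.50, adjusted p = 0.125 with an estimated correlation), with ATF3 (3.66, 4.99 and 6.59) and ATF5 (3.97, 4.97 and 4.54). Cholesterol synthesis was called down in WT cells at 6 h, where 2 of 23 rose and 16 fell (2 and 16 adjusted over the list alone, median -1.35, adjusted p = 0.475 with an estimated correlation). It was called up in KO cells at 24 h, where 9 of 23 rose and 2 fell (10 and 2 adjusted over the list alone, median 0.90, adjusted p = 0.676 with an estimated correlation). Members in WT cells included STARD4 (2.97, 2.59 and 1.96) and MVK (-3.34, -1.17 and -1.46). Markers of undifferentiated myeloid precursors were called down at 24 h, where 2 of 21 rose and 13 fell (2 and 13 adjusted over the list alone, median -1.65, adjusted p = 0.138 with an estimated correlation) in WT cells. In KO cells at that time 1 of 21 rose and 16 fell (2 and 16 adjusted over the list alone, median -2.52, adjusted p = 0.0213 with an estimated correlation). Histone genes were called up at 24 h, where 10 of 16 rose and 2 fell (10 and 2 adjusted over the list alone, median 1.18, adjusted p = 0.380 with an estimated correlation) in WT cells. For KO cells 8 of 16 rose and 2 fell (8 and 2 adjusted over the list alone, median 1.10, adjusted p = 0.502 with an estimated correlation). Macrophage identity was called down in WT cells at 24 h, where 5 of 30 rose and 17 fell (6 and 17 adjusted over the list alone, median -1.58, adjusted p = 0.525 with an estimated correlation). Its largest changes were C1QB (5.45, 6.78 and 6.47) and CEBPA (-3.49, -3.0 and -2.40). Heat shock was called down at the same time, where 1 of 15 rose and 9 fell (1 and 10 adjusted over the list alone, median -0.99, adjusted p = 0.519 with an estimated correlation), with HSPE1 (-0.92, -0.96 and -2.73, called at 24 h). Glycolysis and hypoxia response was called up in KO cells at 12 h, where 10 of 32 rose and 1 fell (10 and 1 adjusted over the list alone, median 0.51, adjusted p = 0.579 with an estimated correlation), with VEGFA (2.23, 2.46 and 2.03) in front. Not called at any time were NRF2 targets (4 to 9 up and 4 to 7 down of 28 in WT cells) and cholesterol efflux and lipid handling (2 to 3 and 5 to 10 of 21). Nor were lysosome (0 to 6 and 4 to 5 of 27) and markers of other cell types (2 to 4 and 1 to 4 of 15).

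Over all genes 3212 genes higher and 4428 lower, then 3568 genes higher and 4609 lower, then 4295 genes higher and 5552 lower, were called in WT cells, 2148 and 2485 of them at all 3 times. In KO cells there were 3434 genes higher and 4785 lower, then 3299 genes higher and 4131 lower, then 3682 genes higher and 4587 lower, 2152 and 2285 of them at all 3 times. The 2 genotypes shared 2439 (519), 2569 (554) and 2832 (745) genes called up and 3300 (998), 2999 (897) and 3448 (1199) called down, with the numbers from independent picking in brackets. Log2 changes in WT and KO cells correlated across genes with r = 0.848, 0.847 and 0.823 (rho = 0.808, 0.820 and 0.802). Counts moved by over 1.5 times with a stricter filter (4076 for WT 6 h, 4593 for WT 12 h, 5654 for WT 24 h, 4390 for KO 6 h, 4027 for KO 12 h and 4650 for KO 24 h), with library weights (11822 for WT 6 h and 13217 for KO 6 h) and with only the libraries compared (4624 for KO 6 h).

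**Figure D2:**
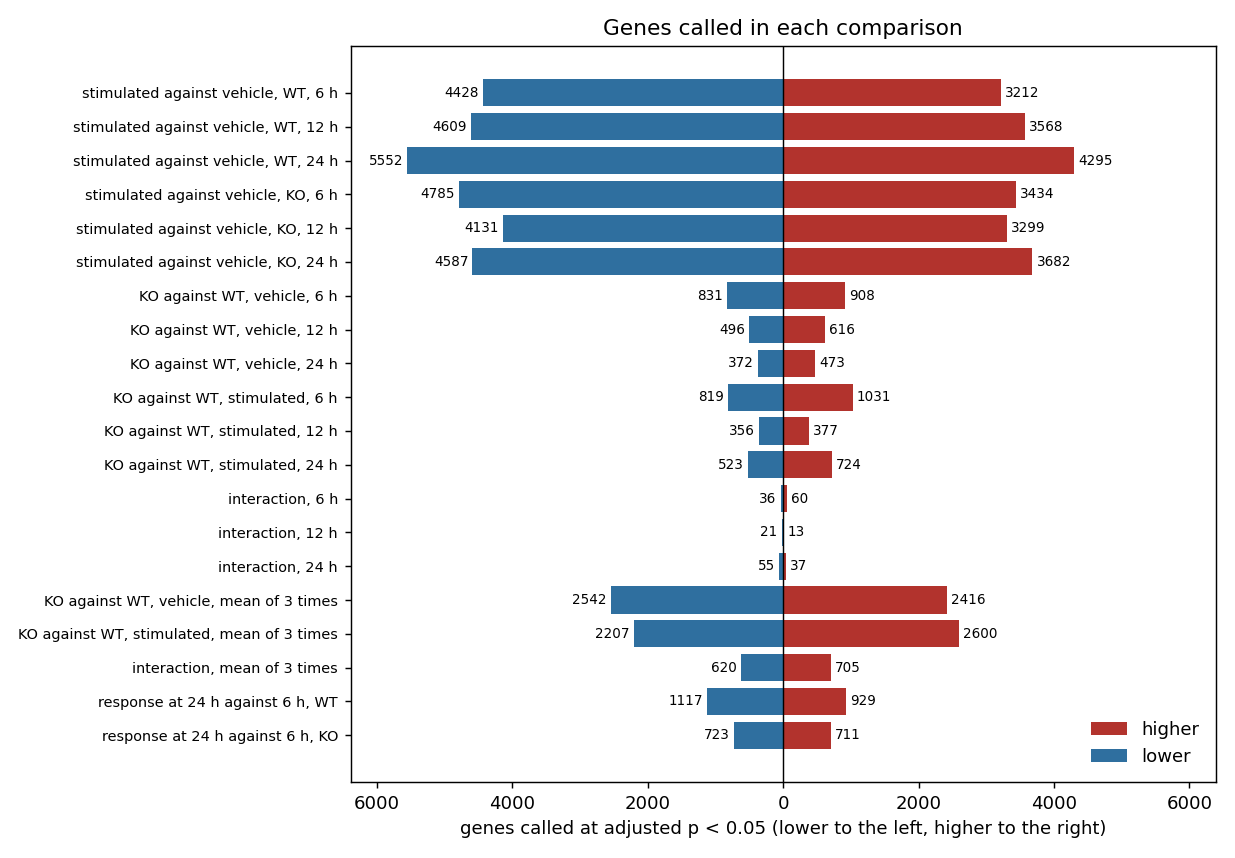
Genes called higher (red, to the right) and lower (blue, to the left) in each comparison at limma adjusted p below 0.05 (horizontal axis, number of genes). The bars ran from 34 genes for the interaction at 12 h to 9847 for stimulation of WT cells at 24 h.

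The second question was how KO cells differed from WT cells without stimulation. Chemokines were lower in vehicle-treated KO cells. CXCL10 was at 0.84 ± 1.04 against 4.13 ± 1.12 in WT at 6 h (n = 3), a change of -3.29 ± 0.73 (adjusted p = 0.00379). At the later times it was -2.90 and -2.78. Other members were lower too, with CXCL1 (-4.54, -3.67 and -2.27), CXCL8 (-4.36, -3.77 and -2.16, called at 6 h and 12 h) and CXCL3 (-3.80, -2.91 and -2.72). The hemoglobin scavenger receptor CD163 (-5.36, -5.58 and -5.31) and the myeloid receptor CLEC5A (-5.39, -4.85 and -4.27) were lower. So were the neuronal filament gene INA (-7.03, -5.99 and -4.85), MAGED1 (-5.57, -5.34 and -5.18), TNNT1 (-5.0, -4.94 and -5.33) and PID1 (-5.52, -4.82 and -4.41). The 6 largest rises included the collagen gene COL10A1 (5.75, 6.37 and 6.41) and the transcription factors SP6 (5.86, 6.70 and 5.68) and POU4F2 (5.14, 5.79 and 5.23). The rest were the neuropeptide NTS (5.78, 5.71 and 6.26), IGFBP5 (5.30, 5.69 and 5.93) and TEX11 (6.50, 5.30 and 4.61). Of the other genes fixed beforehand, IL10 (-2.58) and HMOX1 (-1.72) were lower at 6 h. On the mean of 3 times TNF (-1.18 ± 0.26, adjusted p = 9.11e-04), IL10 (-2.13 ± 0.40), CXCL10 (-2.99 ± 0.42) and HMOX1 (-1.38 ± 0.26) were called lower. The TNF group means lay under log2(10) in both genotypes at all 3 times (1.57 ± 0.24 in WT and 0.31 ± 0.25 in KO cells at 6 h). Those of IL10 and CXCL10 did so in KO cells, and that of IL10 also in WT cells at 12 h and 24 h. ACOD1, IL6, IL1B, IL12B and IFNB1 were not called, with -0.27, 0.14, -0.49, -0.18 and -0.55 on the mean of 3 times. IL10 at 6 h lost its call without WT replicate 1 (-2.27) or KO replicate 2 (-2.19). HMOX1 at 6 h lost its call without KO replicate 1 (-1.34) or WT replicate 2 (-1.54). CXCL10 at 12 h lost its call without KO replicates 1 (-2.30) and 3 (-2.44) or WT replicates 2 (-2.26) and 3 (-2.77). IL10 at 24 h gained a call without KO replicate 2 (-2.53). CXCL10 at 24 h lost its call without KO replicates 1 (-2.34) and 3 (-2.41) or WT replicates 2 (-2.34) and 3 (-2.81). CLEC5A at 24 h lost its call without WT replicates 1 (-3.98) and 2 (-3.99) or KO replicates 1 (-4.30) and 3 (-4.09). Under other settings calls were lost, with only the libraries compared CXCL10 (6 h, 12 h and 24 h), HMOX1 (6 h), INA (12 h and 24 h) and SP6 (24 h), and with a pseudocount of 5 IL10 (6 h), CXCL10 (24 h) and TNF (mean). In vehicle the replicate block gained calls (adjusted p in brackets) for TNF (6 h 0.00908, 12 h 0.0161 and 24 h 0.0455) and HMOX1 (24 h 0.0468). Also gained: HMOX1 (24 h) with only the libraries compared.

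On the mean of 3 times 17 gene lists were called between vehicle-treated KO and WT cells, and chemokines alone held with an estimated correlation. Among chemokines 0 of 24 rose and 17 fell (0 and 17 adjusted over the list alone, median -1.63, adjusted p = 0.00477 with an estimated correlation). Among interferon-stimulated genes 0 of 40 rose and 30 fell (0 and 34 adjusted over the list alone, median -1.45), with IFI44L (-3.38, -3.35 and -4.05, called at 6 h and 24 h), OASL (-3.24, -3.23 and -3.13) and IFIT2 (-3.28, -2.69 and -2.78) (adjusted p = 0.220 with an estimated correlation). For cholesterol synthesis 0 of 23 rose and 20 fell (0 and 21 adjusted over the list alone, median -0.88), with INSIG1 (-2.70, -1.93 and -0.88, called at 6 h and 12 h) and IDI1 (-2.19, -1.68 and -0.96, called at 6 h and 12 h) (adjusted p = 0.125 with an estimated correlation). Of the macrophage identity genes, which mark the mature cell, 1 of 30 rose and 18 fell (2 and 20 adjusted over the list alone, median -1.15). Beside CD163 they included FCGR3A (-4.92, -3.53 and -3.56), SIGLEC1 (-3.06, -3.21 and -3.29) and C1QC (-2.76, -3.24 and -3.04) (adjusted p = 0.0731 with an estimated correlation). Precursor markers moved the other way, and 9 of 21 rose and 2 fell (9 and 4 adjusted over the list alone, median 0.39). The stem cell factor receptor KIT (3.18, 3.62 and 3.97) rose most (adjusted p = 0.315 with an estimated correlation). For NF-kB feedback and targets 2 of 30 rose and 13 fell (2 and 14 adjusted over the list alone, median -0.58), with TNFAIP6 (-3.30, -2.17 and -1.60) and IER3 (-1.67, -1.65 and -2.22) (adjusted p = 0.121 with an estimated correlation). Of the anti-inflammatory mediators 1 of 16 rose and 8 fell (1 and 11 adjusted over the list alone, median -0.62). EBI3 (-4.21, -3.31 and -3.05) fell most (adjusted p = 0.266 with an estimated correlation). For glycolysis and hypoxia response 0 of 32 rose and 14 fell (2 and 16 adjusted over the list alone, median -0.46), with ENO2 (-3.11, -2.74 and -2.66) and HK3 (-1.41, -2.72 and -2.48) (adjusted p = 0.305 with an estimated correlation). Of the NRF2 targets, the antioxidant genes, 0 of 28 rose and 13 fell (0 and 15 adjusted over the list alone, median -0.44), with ME1 (-2.43, -1.95 and -1.44, called at 6 h and 12 h) and FTH1 (-1.66, -1.66 and -1.40) (adjusted p = 0.375 with an estimated correlation). In the lysosome list 0 of 27 rose and 10 fell (2 and 13 adjusted over the list alone, median -0.44), with CTSH (-1.57, -1.92 and -2.14) and CTSB (-1.22, -1.52 and -1.53) (adjusted p = 0.315 with an estimated correlation).

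The remaining calls had small medians. Ubiquitin ligases were called lower, and 0 of 50 rose and 12 fell (0 and 12 adjusted over the list alone, median -0.09). NEDD4L (-1.80, -1.47 and -0.75, called at 6 h and 12 h) and CUL2 (-1.34, -1.20 and -0.70, called at 6 h and 12 h) were members (adjusted p = 0.643 with an estimated correlation). Proteasome genes were also lower, and 0 of 31 rose and 8 fell (0 and 9 adjusted over the list alone, median -0.22). Their largest change was in PSMB6 (-0.76, -0.66 and -0.66, called at 6 h) (adjusted p = 0.598 with an estimated correlation). In the TCA cycle 0 of 28 rose and 6 fell (0 and 8 adjusted over the list alone, median -0.17, adjusted p = 0.475 with an estimated correlation), with IDH1 (-1.53, -1.14 and -0.46, called at 6 h and 12 h). In the integrated stress response 1 of 27 rose and 7 fell (2 and 10 adjusted over the list alone, median -0.36, adjusted p = 0.640 with an estimated correlation), with PHGDH (-2.85, -1.72 and -1.13, called at 6 h). In cholesterol efflux and lipid handling 1 of 21 rose and 4 fell (1 and 7 adjusted over the list alone, median -0.45, adjusted p = 0.378 with an estimated correlation), with SCD (-2.34, -2.35 and -1.99). In antigen presentation 2 of 27 rose and 8 fell (2 and 14 adjusted over the list alone, median -0.38, adjusted p = 0.630 with an estimated correlation). In heat shock 1 of 15 rose and 3 fell (1 and 5 adjusted over the list alone, median -0.31, adjusted p = 0.581 with an estimated correlation). Ubiquitin ligases lost their call without WT replicate 1 at 24 h (-0.06), WT replicate 2 at 6 h (-0.09), 12 h (-0.08) and 24 h (-0.07) or KO replicate 2 at 6 h (-0.09) and 24 h (-0.08). Cholesterol efflux and lipid handling lost its call without WT replicate 1 at 6 h (-0.41), 12 h (-0.38) and 24 h (-0.39), KO replicate 1 at 6 h (-0.44) and 24 h (-0.45), WT replicate 3 at 6 h (-0.40) or KO replicate 3 at 12 h (-0.45). Antigen presentation lost its call without KO replicate 2 at 12 h (-0.35) or WT replicate 3 at 6 h (-0.34), 12 h (-0.33) and 24 h (-0.37). Heat shock lost its call without WT replicate 2 at 6 h (-0.26), 12 h (-0.26) and 24 h (-0.25). Not called were proinflammatory cytokines (2 up and 5 down of 23), E1 and E2 enzymes (3 and 6 of 37), deubiquitinases (1 and 2 of 42) and markers of other cell types (5 and 8 of 15). Proinflammatory cytokines gained a call without WT replicate 1 at 6 h (-0.52) and 24 h (-0.51) or KO replicate 2 at 12 h (-0.51) and 24 h (-0.54).

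Over all genes 908 genes higher and 831 lower, then 616 genes higher and 496 lower, then 473 genes higher and 372 lower, were called between vehicle-treated KO and WT cells, 296 and 241 of them at all 3 times, and 2416 genes higher and 2542 lower on the mean. The count moved by over 1.5 times without WT replicate 1 (982) or KO replicates 1 (1051) and 3 (1136) at 6 h, WT replicates 1 (564) and 3 (636) or KO replicates 1 (449) and 3 (617) at 12 h or WT replicates 1 (410) and 3 (472) or KO replicates 1 (291) and 3 (407) at 24 h. It also moved with a stricter filter (766 for 6 h, 384 for 12 h, 285 for 24 h and 2417 for the mean), with library weights (8673 for 6 h, 4492 for 12 h, 3217 for 24 h and 10013 for the mean), with only the libraries compared (750 for 6 h, 562 for 12 h and 284 for 24 h), with a replicate block (2712 for 6 h, 1775 for 12 h and 1451 for 24 h) and with a minimum log2 change of 1 (2574 for the mean). The difference correlated across genes with GC content at 6 h (rho = 0.279) and with transcript length at 24 h (rho = 0.264).

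The third question was how KO cells differed from WT cells under stimulation. Most cytokines fixed beforehand were not called: TNF (-0.75, -0.51 and -0.05), IL6 (-0.04, 0.69 and 1.07), IL1B (-1.51, -1.37 and -0.89), IL12B (-1.69, -1.68 and 0.19), CXCL10 (0.45, 0.08 and 0.47) and IFNB1 (-0.54, -1.65 and -2.62). IL10 was lower in KO cells at 6 h, 3.63 ± 1.30 against 6.53 ± 1.12 in WT (n = 3, -2.90 ± 0.69, adjusted p = 0.00791), and not called later (-0.59 and -0.07). On the mean of 3 times IL10 (-1.18 ± 0.40, adjusted p = 0.0323) and HMOX1 (-0.92 ± 0.26, adjusted p = 0.00973) were lower, and IFNB1 (-1.61 ± 0.60, adjusted p = 0.0528) and IL1B (-1.26 ± 0.71, adjusted p = 0.219) were not called. The matrix protease MMP9 was lower in KO cells (10.29 ± 1.53 against 15.24 ± 1.39 at 6 h, 30.9-fold, log2 changes -4.95, -4.40 and -3.17). So were the monocyte attractant CCL7 (-4.10, -5.32 and -6.67) and the scavenger receptor CD163 (-5.54, -5.12 and -4.82). INA (-5.15, -6.07 and -5.06), TNNT1 (-3.66, -4.83 and -5.28) and MAGED1 (-5.22, -4.71 and -3.36) were lower here as in vehicle. The largest rises were in COL10A1 (6.65, 6.50 and 4.58), LINC03082 (4.86, 4.56 and 2.98) and CSMD3 (3.67, 4.41 and 4.25). Next were TNFSF12 (4.35, 4.14 and 3.49), TSPAN18 (4.18, 3.70 and 3.36) and GPRC5B (3.36, 3.89 and 3.62). IL10 at 6 h lost its call without WT replicate 1 (-2.49). IL6 at 24 h gained a call without WT replicate 2 (2.23). HMOX1 at 24 h gained a call without WT replicate 2 (-1.57). MMP9 at 24 h lost its call without WT replicates 1 (-2.78) and 3 (-3.34) or KO replicates 1 (-2.78) and 3 (-3.19). LINC03082 at 24 h lost its call without KO replicate 3 (2.76). IL6 on the mean gained a call without WT replicate 2 at 24 h (0.96). IL10 on the mean lost its call without WT replicate 1 at 6 h (-1.05), 12 h (-0.94) and 24 h (-1.15), KO replicate 1 at 6 h (-1.02), 12 h (-1.11) and 24 h (-1.18), WT replicate 2 at 6 h (-1.11) and 24 h (-1.12), KO replicate 2 at 24 h (-1.13) or KO replicate 3 at 6 h (-1.11) and 12 h (-1.17). IL12B on the mean gained a call without KO replicate 2 at 12 h (-1.64). IFNB1 on the mean gained a call without KO replicate 2 at 6 h (-1.86), 12 h (-1.99) and 24 h (-1.87) or WT replicate 3 at 12 h (-1.75). Under other settings calls were lost, with only the libraries compared CSMD3 (6 h and 24 h), TNNT1 (6 h), MMP9 (6 h, 12 h and 24 h), IL10 (6 h and mean), LINC03082 (12 h and 24 h), TSPAN18 (12 h and 24 h), GPRC5B (12 h and 24 h), CCL7 (12 h), ACOD1 (12 h), COL10A1 (24 h), TNFSF12 (24 h), CD163 (24 h) and MAGED1 (24 h), and with a minimum log2 change of 1 HMOX1 (mean). With a replicate block calls were gained (adjusted p in brackets) for ACOD1 (24 h 0.0264), IL1B (mean 0.0465) and IFNB1 (mean 0.0216). Also gained: ACOD1 (24 h) and IFNB1 (mean) with a pseudocount of 5, or with 2 or 4 doubted libraries left out.

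On the mean of 3 times 8 lists were called between stimulated KO and WT cells, and none held with an estimated correlation. In the chemokine list 3 of 24 rose and 10 fell (3 and 13 adjusted over the list alone, median -0.79). Beside CCL7 they included CCL13 (-1.57, -2.94 and -2.40, called at 12 h and 24 h) and CXCL3 (-1.81, -2.0 and -1.62) (adjusted p = 0.174 with an estimated correlation). Antigen presentation genes were higher, and 9 of 27 rose and 0 fell (9 and 0 adjusted over the list alone, median 0.28), with HLA-DOA (0.84, 2.47 and 2.45, called at 12 h and 24 h) (adjusted p = 0.480 with an estimated correlation). In macrophage identity 4 of 30 rose and 10 fell (4 and 11 adjusted over the list alone, median -0.50). VSIG4 (-2.83, -3.27 and -3.04) and LYZ (-2.65, -3.11 and -2.78) were lower (adjusted p = 0.397 with an estimated correlation). Lysosome genes were lower, and 2 of 27 rose and 8 fell (3 and 8 adjusted over the list alone, median -0.33), with CTSL (-1.61, -2.07 and -2.21) and CTSB (-1.20, -1.75 and -1.94) (adjusted p = 0.448 with an estimated correlation). Of the ubiquitin ligases 0 of 50 rose and 7 fell (0 and 6 adjusted over the list alone, median -0.15). The muscle atrophy ligase FBXO32 (-1.48, -1.80 and -1.78), CBLB (-1.77, -1.74 and -1.31) and TRIM38 (-0.76, -0.71 and -0.82) were lower (adjusted p = 0.562 with an estimated correlation). For NRF2 targets 0 of 28 rose and 9 fell (0 and 9 adjusted over the list alone, median -0.39), with TKT (-0.99, -0.85 and -0.83, called at 6 h) (adjusted p = 0.448 with an estimated correlation). For cholesterol efflux and lipid handling 0 of 21 rose and 7 fell (0 and 7 adjusted over the list alone, median -0.41), with NR1H3 (-2.28, -1.66 and -1.60, called at 6 h) (adjusted p = 0.121 with an estimated correlation). Of the histone genes 0 of 16 rose and 6 fell (0 and 8 adjusted over the list alone, median -0.56), with H4C1 (0.66, -2.70 and -2.32, none called) (adjusted p = 0.265 with an estimated correlation). Interferon-stimulated genes, lower in vehicle, were not called here (median -0.14, adjusted p = 0.0802). Here 0 of 40 rose and 3 fell (0 and 1 adjusted over the list alone). Nor were proinflammatory cytokines (1 up and 6 down of 23), with OSM (-3.93, -3.48 and -2.54, called at 6 h and 12 h), CSF3 (-3.75, -2.93 and -1.48, called at 6 h and 12 h) and LIF (-3.72, -2.30 and -1.89, called at 6 h). The lists of E1 and E2 enzymes (3 and 4 of 37) with UBE2D1 (-1.18, -1.01 and -0.73, called at 6 h and 12 h), and deubiquitinases (2 and 2 of 42) were not called. Ubiquitin ligases lost their call without KO replicate 2 at 6 h (0.04). Interferon-stimulated genes gained a call without KO replicate 1 at 6 h (-0.18), WT replicate 2 at 12 h (-0.20), WT replicate 3 at 6 h (-0.18) and 24 h (-0.21) or KO replicate 3 at 6 h (-0.18). Proinflammatory cytokines gained a call without KO replicate 2 at 12 h (-0.22) and 24 h (-0.45) or WT replicate 3 at 24 h (-0.31).

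Over all genes 1031 genes higher and 819 lower, then 377 genes higher and 356 lower, then 724 genes higher and 523 lower, were called between stimulated KO and WT cells, 125 and 122 of them at all 3 times, and 2600 genes higher and 2207 lower on the mean. The vehicle and stimulated comparisons shared no library. On the mean 1014 (296) genes were higher and 1001 (264) lower in both, with independent picking in brackets. Mean changes correlated across genes with r = 0.537 (rho = 0.508). Like-numbered vehicle and stimulated libraries shared deviations (r = 0.0387 to 0.589), which may raise overlap and r. The count moved by over 1.5 times without WT replicates 1 (932) and 2 (1173) at 6 h, WT replicates 1 (329) and 3 (383) or KO replicates 1 (247) and 3 (382) at 12 h or KO replicates 1 (339) and 3 (519) or WT replicate 3 (444) at 24 h. It also moved with a stricter filter (727 for 6 h, 222 for 12 h, 648 for 24 h and 2243 for the mean), with library weights (5894 for 6 h, 3589 for 12 h, 4641 for 24 h and 9220 for the mean), with only the libraries compared (111 for 6 h, 47 for 12 h, 3 for 24 h and 3180 for the mean), with a replicate block (2932 for 6 h, 1504 for 12 h and 2464 for 24 h), with 2 doubted libraries left out (675 for 24 h) and with a minimum log2 change of 1 (2241 for the mean). The difference at 6 h correlated across genes with GC content (rho = 0.429) and transcript length (rho = -0.252). KO replicate 2 at 6 h and WT replicate 3 at 24 h stood apart from their groups.

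**Figure D3:**
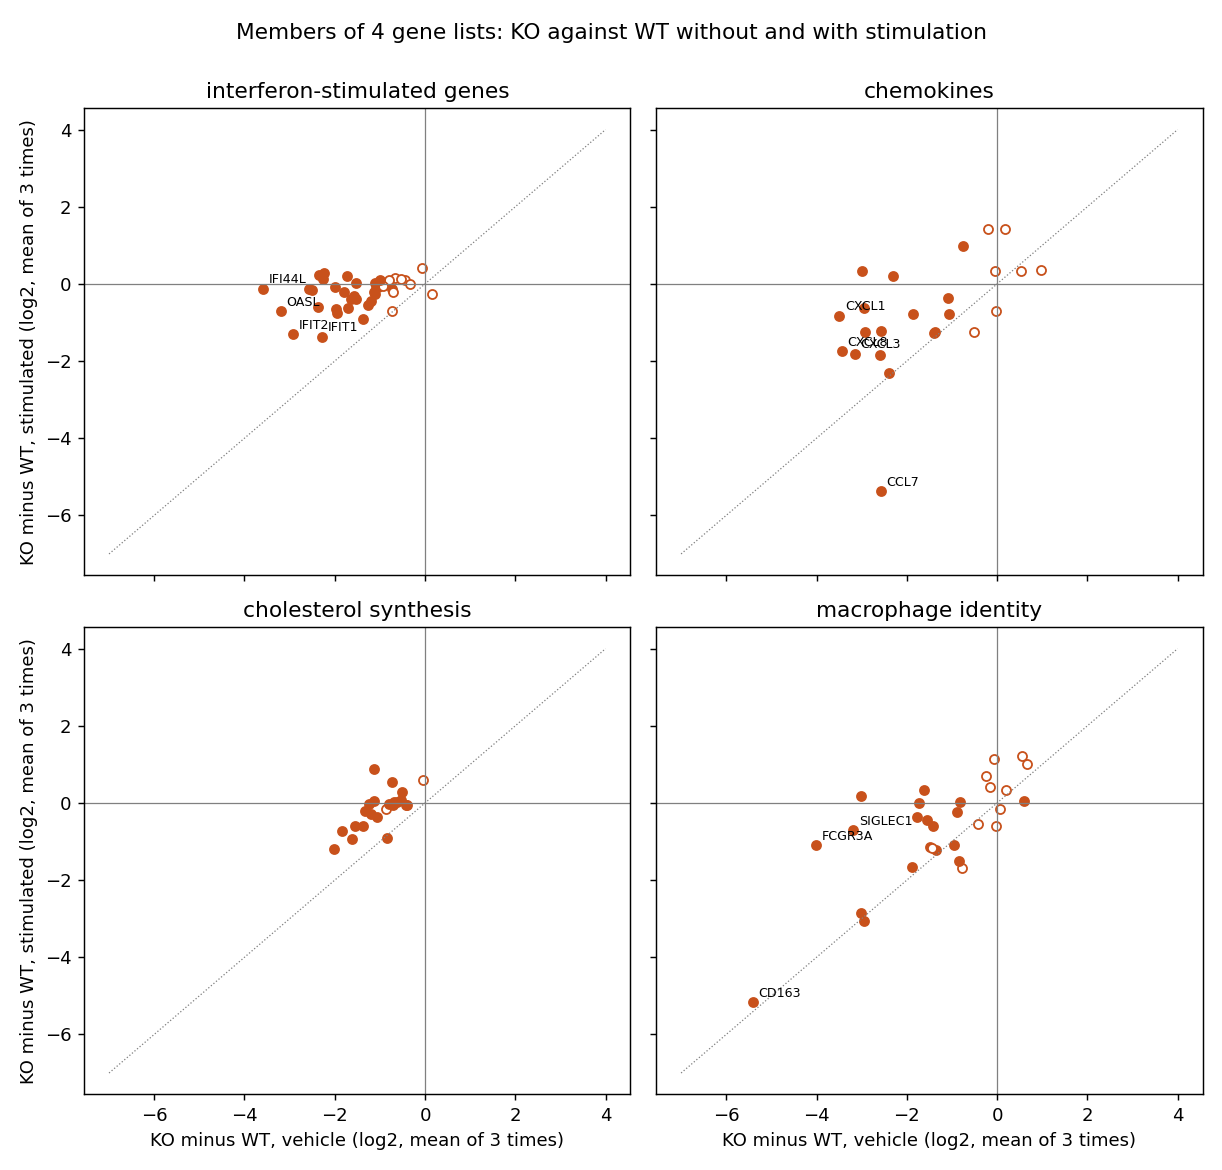
KO minus WT log2 change on the mean of 3 times for members of 4 gene lists, in vehicle (horizontal axis) against stimulated cells (vertical axis), with filled points for genes called in vehicle and a dotted line of equal values. The median of interferon-stimulated genes was -1.45 in vehicle and -0.14 with stimulation.

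The fourth question was whether the response to stimulation differed between KO and WT cells, tested as an interaction. On the mean of 3 times the response of CXCL10 was larger in KO cells by 3.32 ± 0.59 (adjusted p = 7.48e-04, n = 3 per group). KO against WT it was -2.99 in vehicle, with KO levels under log2(10), and 0.33 with stimulation (adjusted p = 0.630). Stimulated levels (14.7 to 16.2) near the top (16.75) may hide a difference. EBI3, a subunit shared by IL-27 and IL-35, also responded more in KO cells, by 4.41 ± 0.50. Higher responses in KO cells were called for the nuclease DNASE1L3 (4.16), the T cell costimulator TNFRSF9 (3.71), the death ligand FASLG (3.48), COLEC12 (3.51) and IFI44L (3.47). Lower responses there were called for the gap junction gene GJA1 (-5.18), the calcium pump inhibitor PLN (-4.88), RASSF10 (-4.75), HSPB3 (-4.64), STON1-GTF2A1L (-4.10) and C11orf96 (-4.03). Most of these differences lay in vehicle, where all 12 genes were called between KO and WT, against 3 with stimulation. ACOD1 responded less in KO cells (-2.22 ± 0.39, adjusted p = 5.61e-04), and here the difference lay with stimulation (-0.27 in vehicle, -2.49 with stimulation). Responses of TNF, IL6, IL1B, IL10, IL12B, IFNB1 and HMOX1 were not shown to differ (0.75, 0.43, -0.77, 0.95, -0.88, -1.05 and 0.46). At single times the replicate block gained calls (adjusted p in brackets) for TNFRSF9 (6 h 0.0307 and 12 h 0.0495), COLEC12 (6 h 0.0297, 12 h 0.0158 and 24 h 0.00843), GJA1 (6 h 0.0113 and 24 h 0.0414), CXCL10 (6 h 0.0434), EBI3 (12 h 0.0123), HSPB3 (12 h 0.0425), STON1-GTF2A1L (12 h 0.0337 and 24 h 0.0415) and DNASE1L3 (24 h 0.0159). Also gained: TNFRSF9 (6 h and 12 h), GJA1 (6 h), RASSF10 (6 h), EBI3 (12 h), COLEC12 (12 h and 24 h), HSPB3 (12 h and 24 h) and DNASE1L3 (24 h) with a pseudocount of 5; EBI3 (12 h) with only the libraries compared; TNFRSF9 (6 h) with 2 doubted libraries left out; TNFRSF9 (6 h), COLEC12 (6 h) and DNASE1L3 (24 h) with 4 doubted libraries left out.

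In the mean interaction 11 lists were called and none held with an estimated correlation. Interferon-stimulated genes responded more in KO cells, from a lower vehicle level (KO against WT medians -1.45 in vehicle and -0.14 with stimulation), and 17 of 40 rose and 0 fell (26 and 0 adjusted over the list alone, median 1.10). Beside IFI44L they included MX1 (2.58) and IFI27 (2.51) (adjusted p = 0.283 with an estimated correlation). Among chemokines 7 of 24 rose and 1 fell (10 and 1 adjusted over the list alone, median 0.91). Beside CXCL10 they included CCL7 (-2.79), CXCL1 (2.67) and CXCL11 (2.51) (adjusted p = 0.104 with an estimated correlation). For NF-kB feedback and targets 7 of 30 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.50), with BIRC3 (1.78) and ICAM1 (1.75) (adjusted p = 0.0946 with an estimated correlation). For antigen presentation 9 of 27 rose and 0 fell (14 and 1 adjusted over the list alone, median 0.42), with HLA-DMA (2.72) and HLA-DRA (2.67) (adjusted p = 0.181 with an estimated correlation). For cholesterol synthesis 8 of 23 rose and 0 fell (13 and 0 adjusted over the list alone, median 0.77), with STARD4 (2.01) and SQLE (1.28) (adjusted p = 0.172 with an estimated correlation). For macrophage identity 8 of 30 rose and 0 fell (11 and 1 adjusted over the list alone, median 0.35), with C1QC (3.19) and FCGR3A (2.92) (adjusted p = 0.384 with an estimated correlation). Of the interferon-gamma-induced GTPases and regulators 6 of 28 rose and 1 fell (10 and 2 adjusted over the list alone, median 0.52), with CIITA (2.70), SECTM1 (2.34) and GBP7 (-1.76) (adjusted p = 0.397 with an estimated correlation). In glycolysis and hypoxia response 5 of 32 rose and 0 fell (10 and 1 adjusted over the list alone, median 0.45, adjusted p = 0.446 with an estimated correlation). In the TCA cycle 2 of 28 rose and 0 fell (5 and 1 adjusted over the list alone, median 0.27, adjusted p = 0.372 with an estimated correlation). Among anti-inflammatory mediators 2 of 16 rose and 1 fell (2 and 1 adjusted over the list alone, median 0.36, adjusted p = 0.468 with an estimated correlation). Histone genes were called down with no member called (median -0.37, adjusted p = 0.562 with an estimated correlation). Ubiquitin ligases (2 up and 2 down), E1 and E2 enzymes (2 and 2) and deubiquitinases (2 and 0) were not called. Members included FBXO32 (-2.21), CBLB (-1.65), UBE2L6 (0.84) and STAMBPL1 (1.58). Anti-inflammatory mediators lost their call without KO vehicle replicate 1 at 6 h (0.34), 12 h (0.39) and 24 h (0.30), KO stimulated replicate 2 at 6 h (0.31), 12 h (0.38) and 24 h (0.38), WT stimulated replicate 2 at 12 h (0.35), WT stimulated replicate 3 at 6 h (0.38) and 24 h (0.31) or KO vehicle replicate 3 at 12 h (0.25) and 24 h (0.39). Histone genes lost their call without WT vehicle replicate 1 at 6 h (-0.30), 12 h (-0.34) and 24 h (-0.29), KO stimulated replicate 1 at 6 h (-0.27), 12 h (-0.29) and 24 h (-0.27), KO vehicle replicate 2 at 6 h (-0.33) and 24 h (-0.36), WT vehicle replicate 2 at 12 h (-0.26), KO stimulated replicate 2 at 12 h (-0.37), WT stimulated replicate 2 at 24 h (-0.31), WT stimulated replicate 3 at 6 h (-0.28), 12 h (-0.24) and 24 h (-0.37), KO vehicle replicate 3 at 6 h (-0.34), 12 h (-0.26) and 24 h (-0.27) or KO stimulated replicate 3 at 6 h (-0.37).

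Over all genes 60 genes higher and 36 lower, then 13 genes higher and 21 lower, then 37 genes higher and 55 lower, were called for the interaction and 705 genes higher and 620 lower on the mean. The single-time counts moved by over 1.5 times without WT vehicle replicates 1 (41), 2 (56) and 3 (63), WT stimulated replicate 1 (51), KO vehicle replicates 1 (36) and 3 (52) or KO stimulated replicates 1 (41) and 3 (58) at 6 h, WT vehicle replicates 1 (11), 2 (19) and 3 (4), WT stimulated replicates 1 (19), 2 (76) and 3 (18), KO vehicle replicates 1 (8), 2 (83) and 3 (15) or KO stimulated replicates 1 (16) and 3 (22) at 12 h or WT vehicle replicates 1 (29) and 3 (45), KO vehicle replicates 1 (18), 2 (169) and 3 (24), KO stimulated replicates 1 (26), 2 (202) and 3 (31) or WT stimulated replicates 2 (174) and 3 (36) at 24 h. Counts also moved with a stricter filter (8 for 6 h, 0 for 12 h, 9 for 24 h and 480 for the mean), with a pseudocount of 5 (186 for 6 h, 82 for 12 h and 157 for 24 h), with library weights (2919 for 6 h, 1117 for 12 h, 2373 for 24 h and 6098 for the mean), with only the libraries compared (0 for 6 h, 4 for 12 h and 4 for 24 h), with a replicate block (219 for 6 h, 115 for 12 h, 427 for 24 h and 2261 for the mean) and with 2 doubted libraries left out (188 for 6 h).

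The fifth question was whether the response changed within each genotype, as the log2 response at 24 h minus that at 6 h. In WT cells the responses of TNF (-2.23 ± 0.63, adjusted p = 0.0224), IL6 (-3.34 ± 0.89, adjusted p = 0.0171) and IL10 (-4.42 ± 0.98, adjusted p = 0.00487) were lower at 24 h (n = 3 per group). The fall of HMOX1 at 6 h was gone at 24 h, a difference of 3.11 ± 0.63. In KO cells the early fall of HMOX1 was lost as well (2.59 ± 0.63, adjusted p = 0.0112). No call was made there for TNF, IL6, IL10, ACOD1, IL1B, IL12B, CXCL10 or IFNB1 (-1.73, -2.15, -2.28, 0.34, -0.47, -2.63, -0.23 and -3.05). In WT cells ACOD1, IL1B, IL12B, CXCL10 and IFNB1 were not called (-1.75, -0.48, -4.74, 0.26 and -1.81). The largest positive differences in WT cells were in the prostaglandin E synthase PTGES (5.60), the histone genes H4C4 (5.74) and H3C6 (5.23), LRRC31 (5.86), MAP1LC3C (5.55) and EPCIP (5.52). The largest negative ones were in THSD7B (-7.10), GPR31 (-6.77), TTBK1 (-6.21), KCNV1 (-6.12), FCAMR (-6.10) and SERPINB4 (-6.07). Positive differences in KO cells were largest in the hormone STC2 (6.64), the serine synthesis enzyme PSAT1 (6.54), PADI2 (5.79), CYGB (5.59), LHX1 (5.31) and NDRG4 (5.27). Negative ones included the oxidase DUOX2 (-7.26), FSTL3 (-7.04), XCL1 (-6.34), RTL4 (-6.18) and LINC01088 (-5.96). TNF in WT cells lost its call without stimulated replicate 2 at 6 h (-2.01), vehicle replicate 2 at 24 h (-2.03), vehicle replicate 3 at 6 h (-2.09) or stimulated replicate 3 at 24 h (-1.79). IL6 in WT cells lost its call without stimulated replicate 3 at 24 h (-2.57). IL12B in WT cells gained a call without stimulated replicate 2 at 24 h (-6.34). LHX1 in KO cells lost its call without vehicle replicate 1 at 6 h (4.44), vehicle replicate 2 at 24 h (4.60) or stimulated replicate 2 at 24 h (4.84). Under other settings calls were lost, with only the libraries compared TNF (WT), IL6 (WT) and RTL4 (KO), and with 2 or 4 doubted libraries left out TNF (WT) and IL6 (WT). Calls gained with a replicate block (adjusted p in brackets) were IL12B (WT 0.0128) and TNF (KO 0.0135).

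Markers of undifferentiated precursors fell more at 24 h than at 6 h in both genotypes, and this call held with an estimated correlation. Among them 1 of 21 rose and 10 fell (1 and 13 adjusted over the list alone, median -1.80), with FLT3 (-4.47) and MS4A3 (-3.75) (adjusted p = 0.0186 with an estimated correlation) in WT cells. In KO cells 0 of 21 rose and 13 fell (1 and 14 adjusted over the list alone, median -2.33), with CD34 (-4.95) and MS4A3 (-4.92) (adjusted p = 5.34e-04 with an estimated correlation). Integrated stress response genes were called higher in WT cells, where 12 of 27 rose and 0 fell (22 and 1 adjusted over the list alone, median 1.98), with PSAT1 (3.88) and ASNS (3.19) (adjusted p = 0.131 with an estimated correlation). So they were in KO cells, where 17 of 27 rose and 0 fell (20 and 0 adjusted over the list alone, median 2.02, adjusted p = 0.0570 with an estimated correlation), with SLC6A9 (4.35) and AARS1 (3.93). Of the proinflammatory cytokines 0 of 23 rose and 5 fell (0 and 7 adjusted over the list alone, median -1.81), with CSF2 (-5.11) and LIF (-4.95) (adjusted p = 0.317 with an estimated correlation) in WT cells. For these 0 of 23 rose and 4 fell (1 and 6 adjusted over the list alone, median -1.73, adjusted p = 0.207 with an estimated correlation) in KO cells. In oxidative phosphorylation 0 of 30 rose and 10 fell (1 and 13 adjusted over the list alone, median -0.73, adjusted p = 0.367 with an estimated correlation) in WT cells. It was called in KO cells too, where 0 of 30 rose and 3 fell (0 and 6 adjusted over the list alone, median -0.50, adjusted p = 0.447 with an estimated correlation). In cholesterol synthesis 3 of 23 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.83, adjusted p = 0.596 with an estimated correlation) in WT cells. The same list was called in KO cells, where 6 of 23 rose and 0 fell (14 and 0 adjusted over the list alone, median 1.39), with MSMO1 (3.16) and DHCR7 (2.83) (adjusted p = 0.292 with an estimated correlation). Of the cell cycle genes 0 of 32 rose and 3 fell (0 and 3 adjusted over the list alone, median -1.42, adjusted p = 0.526 with an estimated correlation) in WT cells. In KO cells 0 of 32 rose and 1 fell (0 and 1 adjusted over the list alone, median -0.81, adjusted p = 0.741 with an estimated correlation). Of the histone genes 6 of 16 rose and 0 fell (6 and 0 adjusted over the list alone, median 1.39, adjusted p = 0.269 with an estimated correlation) in WT cells. The KO list gave a call as well, and 3 of 16 rose and 0 fell (4 and 0 adjusted over the list alone, median 1.14, adjusted p = 0.367 with an estimated correlation). Called in WT cells alone were TCA cycle, proteasome, immediate early and heat shock genes (medians -0.46, -0.27, 0.91 and -0.58, adjusted p = 0.397, 0.708, 0.475 and 0.530 with an estimated correlation). Chemokines and lysosome genes were called in KO cells alone (medians -1.42 and 0.61, adjusted p = 0.127 and 0.483 with an estimated correlation), with CCL1 (-4.36). Over all genes 929 genes higher and 1117 lower were called in WT and 711 genes higher and 723 lower in KO cells. The count moved by over 1.5 times without vehicle replicate 1 at 6 h (1268) in WT and vehicle replicate 2 at 24 h (939) or vehicle replicate 3 at 6 h (889) in KO cells. It also moved with library weights (5659 for WT and 5850 for KO), with only the libraries compared (932 for WT and 609 for KO), with a replicate block (3242 for WT and 2485 for KO) and with a stricter filter (897 for KO).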

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

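Tests of ACOD1 in vehicle libraries, of poor libraries at 12 h and 24 h and of transcript length in 2 libraries were chosen only after the result was seen, and the others before. Responses that differed between genotypes or between times were marked because the difference itself was tested: 96, 34 and 92 genes for the interaction at 6, 12 and 24 h, 1325 on the mean of 3 times, and 2046 in WT and 1434 in KO cells for 24 h against 6 h. Named genes with a tested difference between genotypes were EBI3 (4.41), DNASE1L3 (4.16), TNFRSF9 (3.71), COLEC12 (3.51), FASLG (3.48), IFI44L (3.47), GJA1 (-5.18), PLN (-4.88), RASSF10 (-4.75), HSPB3 (-4.64), STON1-GTF2A1L (-4.10), C11orf96 (-4.03), ACOD1 (-2.22) and CXCL10 (3.32). Between times in WT cells they were LRRC31 (5.86), H4C4 (5.74), PTGES (5.60), MAP1LC3C (5.55), EPCIP (5.52), H3C6 (5.23), THSD7B (-7.10), GPR31 (-6.77), TTBK1 (-6.21), KCNV1 (-6.12), FCAMR (-6.10), SERPINB4 (-6.07), TNF (-2.23), IL6 (-3.34), IL10 (-4.42) and HMOX1 (3.11). In KO cells they were STC2 (6.64), PSAT1 (6.54), PADI2 (5.79), CYGB (5.59), LHX1 (5.31), NDRG4 (5.27), DUOX2 (-7.26), FSTL3 (-7.04), XCL1 (-6.34), RTL4 (-6.18), LINC01088 (-5.96) and HMOX1 (2.59). List medians called between genotypes with the preset correlation, of which none held with an estimated correlation, were those of anti-inflammatory mediators (0.36), chemokines (0.91), NF-kB feedback and targets (0.50), interferon-stimulated genes (1.10), interferon-gamma-induced GTPases and regulators (0.52), antigen presentation (0.42), TCA cycle (0.27), glycolysis and hypoxia response (0.45), cholesterol synthesis (0.77), macrophage identity (0.35) and histone genes (-0.37). Between times, where undifferentiated myeloid precursor markers alone held in each genotype with an estimated correlation, they were proinflammatory cytokines (-1.81), TCA cycle (-0.46), oxidative phosphorylation (-0.73), integrated stress response (1.98), proteasome core and cap (-0.27), cholesterol synthesis (0.83), undifferentiated myeloid precursor markers (-1.80), cell cycle (-1.42), immediate early genes (0.91), heat shock (-0.58) and histone genes (1.39) in WT cells, and proinflammatory cytokines (-1.73), chemokines (-1.42), oxidative phosphorylation (-0.50), integrated stress response (2.02), cholesterol synthesis (1.39), lysosome (0.61), undifferentiated myeloid precursor markers (-2.33), cell cycle (-0.81) and histone genes (1.14) in KO cells.

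Counts of called genes were set against counts from libraries split at random across the groups. For each of the 12 comparisons of 2 groups, 1 of 10 splits reached the real count, namely the real one, and 10 splits are too few for a share under 0.05. The highest other counts were 2, 1 and 1 against 7640, 8177 and 9847 for stimulated WT cells, 3388, 0 and 0 against 8219, 7430 and 8269 for KO cells, 0, 0 and 0 against 1739, 1112 and 845 for KO against WT in vehicle and 9, 12 and 99 against 1850, 733 and 1247 with stimulation. For the interaction 15, 10 and 11 of 100 splits reached the real counts, with highest others of 1437, 974 and 1853, and for 24 h against 6 h 7 in WT (highest other 2608 against 2046) and 12 in KO cells (4419 against 1434). These shares are not under 0.05, but for these 5 counts they do not measure chance alone. A split that keeps the real division of 1 treatment carries the real difference within that treatment into the tested one. These splits therefore cannot decide whether chance gave these 5 counts, found without the replicate block (with it they were 219, 115, 427, 3242 and 2485, not split). The splits as large kept the real division of 1 treatment in 12 of 15, 10 of 10 and 11 of 11 for the interaction, 7 of 7 in WT and 12 of 12 in KO cells. Splits that mixed the groups in both treatments reached at most 439, 1 and 2 genes for the interaction, and 108 and 119 for 24 h against 6 h, so only at 6 h did a full mixing reach the real count. On the mean of 3 times 1 of 100 splits reached the real count in vehicle (1665 against 4958), 1 with stimulation (2507 against 4807) and 1 for the interaction (228 against 1325).

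Interferon-stimulated genes were lower in vehicle-treated KO than WT cells by a median of -1.45 on the mean of 3 times. Against poor libraries as the source, the median was -1.39 at 12 h and -1.42 at 24 h, where no vehicle library was doubted, and at most -0.89 with 1 left out (the mean list call was lost, adjusted p = 0.220 with an estimated correlation), against transcript length or GC content it stayed at -1.40 after removal of that trend, and against ACOD1 itself its highest value in the 9 WT vehicle libraries was 0.86, under log2(10). That KO cells were less far along differentiation could not be settled: within WT libraries the macrophage identity and interferon-stimulated means had r = -0.544 (permutation p = 0.131, rho = -0.317, permutation p = 0.409, r = -0.493 without the 2 farthest), and within KO libraries r = 0.680 (permutation p = 0.0420, rho = 0.633, permutation p = 0.0770, r = 0.672 without the 2 farthest). The bound of -0.5 written in advance for a rejection was met in WT libraries but not beyond its spread, a condition added after the values were seen. A lower resting interferon tone in the KO line remains possible, and clonal differences between the lines stay open.

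Stimulated KO replicate 2 at 6 h and WT replicate 3 at 24 h stood apart from their groups (mean r = 0.839 and 0.870). A swapped genotype or treatment label is argued against by a lowest margin towards the own label of 0.868, and a swapped time was not tested. Deviations from the other replicates ran with transcript length (weaker rho = -0.457), which may reflect RNA fragmentation, but WT replicate 3 libraries overall ran from -0.588 to -0.396 and KO vehicle replicate 2 at 6 h had -0.538, so length does not single these 2 out. With GC content rho was 0.525 for the KO library and 0.233 for the WT library, and since the second lies between the bound for this cause (0.3) and the bound against it (0.1), GC content stays open.

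Of the 100 highest genes 58 were pseudogenes, against 11.5% of kept genes. Over 51 pairs the parents lay lower by a median of -5.22, as in FTL (11.63, against 16.22 for FTLP3) and RPL13A (8.18, against 15.86 for RPL13AP5), which is consistent with reads of spliced parents being assigned to their processed pseudogenes. Loss of reads across exon junctions could add to this, and 673 single-exon protein-coding genes lay above 14564 with more exons by a median of 0.51 (95% bootstrap interval 0.215 to 0.831), over the bound of 0.5 written in advance but not beyond its spread, a condition added after the value was seen. Levels of the parents, and of single-exon genes, may therefore be off, and how far this reaches other genes stays open.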

How the results depend on the processing

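Leaving out 2 or 4 doubted libraries was chosen after seeing the data, and all other settings before. Counts of the stimulation comparisons and of the means of 3 times kept their size when any 1 library was left out, and all comparisons did so with no filter, median centring, quantile normalization or no mean-variance trend. Unknown depth limits low genes to an unknown degree. Leaving out 1 library leaves groups of 2, with the spread pooled by limma over all groups, and library weights, which ran from 0.103 to 5.96, did not reach convergence. With a stricter filter fewer genes are tested and with only the libraries compared fewer samples give the spread, and for the other settings the cause was not tested.

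Gene counts that moved by over 1.5 times follow. With a stricter filter they were for stimulation 4076 (WT 6 h), 4593 (WT 12 h), 5654 (WT 24 h), 4390 (KO 6 h), 4027 (KO 12 h) and 4650 (KO 24 h), for KO against WT in vehicle 766 (6 h), 384 (12 h), 285 (24 h) and 2417 (the mean), for KO against WT with stimulation 727 (6 h), 222 (12 h), 648 (24 h) and 2243 (the mean), for the interaction 8 (6 h), 0 (12 h), 9 (24 h) and 480 (the mean) and for 24 h against 6 h 897 (KO). A pseudocount of 5 gave for the interaction 186 (6 h), 82 (12 h) and 157 (24 h). Library weights gave for stimulation 11822 (WT 6 h) and 13217 (KO 6 h), for KO against WT in vehicle 8673 (6 h), 4492 (12 h), 3217 (24 h) and 10013 (the mean), for KO against WT with stimulation 5894 (6 h), 3589 (12 h), 4641 (24 h) and 9220 (the mean), for the interaction 2919 (6 h), 1117 (12 h), 2373 (24 h) and 6098 (the mean) and for 24 h against 6 h 5659 (WT) and 5850 (KO). With only the libraries compared the counts were for stimulation 4624 (KO 6 h), for KO against WT in vehicle 750 (6 h), 562 (12 h) and 284 (24 h), for KO against WT with stimulation 111 (6 h), 47 (12 h), 3 (24 h) and 3180 (the mean), for the interaction 0 (6 h), 4 (12 h) and 4 (24 h) and for 24 h against 6 h 932 (WT) and 609 (KO). A replicate block, which lost no call of a named gene or list and gained 25 and 11, gave for KO against WT in vehicle 2712 (6 h), 1775 (12 h) and 1451 (24 h), for KO against WT with stimulation 2932 (6 h), 1504 (12 h) and 2464 (24 h), for the interaction 219 (6 h), 115 (12 h), 427 (24 h) and 2261 (the mean) and for 24 h against 6 h 3242 (WT) and 2485 (KO). With a minimum log2 change of 1 there were for KO against WT 2574 (vehicle mean) and 2241 (stimulated mean). Without the 2 doubted libraries stimulated KO against WT had 675 (24 h) and the interaction 188 (6 h). Leaving out each library in turn moved counts within ranges, which were for KO against WT in vehicle 6 h 982 to 1525, 12 h 449 to 1141 and 24 h 291 to 873, for KO against WT with stimulation 6 h 932 to 1950, 12 h 247 to 890 and 24 h 339 to 1860, for the interaction 6 h 36 to 117, 12 h 4 to 83 and 24 h 18 to 202 and for 24 h against 6 h WT 1268 to 1978 and KO 889 to 1732.

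Lists gained with a replicate block were oxidative phosphorylation (WT 6 h), E1 and E2 enzymes (WT 12 h) and proteasome (KO 12 h and stimulated 6 h). Also gained were precursor markers (KO 12 h and vehicle 6 h), immediate early genes (vehicle 24 h) and glycolysis and hypoxia response (interaction 12 h). On the vehicle mean proinflammatory cytokines, TLR and interferon receptor signalling and cell cycle were gained. Of the list calls fry gained 22 and lost 62. Without stimulated KO replicate 2 of the same time these list medians changed sign (range with each library left out in brackets). The deubiquitinases in the interaction at 6 h went from -0.07 to 0.27 (-0.25 to 0.27). The integrated stress response in stimulated cells at 24 h went from 0.13 to -0.20 (-0.20 to 0.61). A change of sign counted as a reversal only where a setting passed the threshold, and 408 others changed sign while past it under neither, 253 of them list tests with 1 library left out. Named-gene calls gained (lost) numbered 52 (0) with library weights, 12 (5) with a pseudocount of 5, 5 (41) with only the libraries compared, and 4 (5) and 6 (5) without the 2 or 4 doubted libraries. List calls gained (lost) numbered 21 (11) without the 2 doubted libraries, with 1 reversed (the deubiquitinases above, 0.27), and 26 (11) without the 4. With 1 library left out named-gene calls gained (lost) numbered 31 (107) and list calls 154 (156). DESeq2 and edgeR were not applicable, since the values are not counts.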

Other observations

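No test in this part was chosen after the result was seen. The inflammasome and pyroptosis list was not called on the mean in vehicle (3 up and 9 down of 22) or with stimulation (3 and 5). Single members were lower in KO cells: the decoy receptor for IL-1, IL1R2 (-2.55, -3.19 and -2.90, called at 12 h and 24 h in vehicle, -2.83, -3.58 and -3.29 with stimulation), and the pore-forming gasdermin GSDME (-1.88, -1.46 and -1.41, and -1.31, -1.73 and -1.13, called at 6 h and 12 h).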
